A study of Drosophila melanogaster with 72 samples.

How the data were processed

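Gene expression was measured by RNA sequencing of skeletal muscle of Drosophila melanogaster in 72 libraries. Per the labels, RNA was extracted with Trizol and sequenced as stranded mRNA libraries with standard Illumina protocols. The strain B3 is the parental line and O1 and O3 are lines with delayed aging. The labels put 18 libraries in an age experiment (B3, O1 and O3 at 1 and 6 weeks), 31 in a day course of the same strains and 23 in a day course of transgenic flies. Day-course libraries were taken at ZT0, ZT6, ZT12 and ZT18, where ZT (zeitgeber time) counts hours of the lighting schedule. The transgenic lines are mhc, which carries the muscle driver Mhc-Gal4, and mhc>timeless, in which that driver expresses the clock gene timeless (tim). Groups held 3 libraries, except B3 and O3 at ZT6, B3 at ZT18 and mhc>timeless at ZT0 with 2 each and O1 at ZT18 with 1. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical.

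The authors deposited one table of raw counts per library, whole numbers of reads per gene with no normalization. BWA, STAR, HTSeq and the genome build dm3 are named, with no version or role, per the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. Each table listed 15682 genes by symbol, of which 543 had no count in any library. The 37 rows of mitochondrially encoded genes held 0 counts in all libraries, so the list of the mitochondrially encoded respiratory chain had 0 measured members and was not tested. Rows that name no gene were left out of library totals and tests. The share of reads in no annotated feature was 13.0 to 27.9% in the age experiment, 7.11 to 16.5% in the day course and 7.12 to 10.2% in the transgenic experiment. Ambiguous reads took 2.72 to 3.80%, 2.10 to 2.38% and 2.37 to 2.57%. Reads without a unique position came to 0.419 to 0.686 per 100 counted reads in the age experiment, against 19.8 to 45.4 and 7.53 to 11.8 in the other experiments. Such reads may therefore have been handled differently before counting, which was not tested. Genes with near-identical copies, such as the Hsp70, Jon, Lys, Cec, Acp and Mst families, are uncertain for that reason.

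Counts were analysed in R 4.3.3 with edgeR 4.0.16, in 1 model per experiment with a mean per group. Genes were filtered with filterByExpr by group, which left 12445 genes in the age experiment, 12295 in the day course and 12727 in the transgenic experiment, and libraries were scaled with TMM factors of 0.891 to 1.09, 0.956 to 1.06 and 0.971 to 1.03. The common biological coefficient of variation was 0.340, 0.148 and 0.232, with 12, 19 and 15 residual degrees of freedom. Tests were edgeR quasi-likelihood F-tests with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05 with no fold threshold. All adjusted p-values of single genes given here come from these tests. Time of day and its interactions with strain or genotype were joint tests of the time-point means, with no shape of the daily curve assumed. Amplitude is the highest minus the lowest time-point mean on the log2 scale. Contrasts over the day compare the means of the 4 time points with equal weight. Values are given as log2 fold change ± SE or as CPM (counts scaled to the effective library size) ± SD, and log2 CPM used a prior count of 0.5.

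Gene lists were written before the data were examined: 18 of pathways and 13 of markers of other cell types and of sex. Lists with at least 5 measured members were tested in contrasts with a direction by camera of limma 3.58.1 with an estimated inter-gene correlation, adjusted over the lists of a comparison. Calls of single members were also adjusted over the list alone. Genes named for a comparison are the core clock genes, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap of CPM between groups, the 12 smallest p-values of a joint test, and up to 4 members by smallest p of each called list. Members of other lists are named as examples of their list. The main design, the alternatives and this rule were fixed before the data were examined.

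Library totals were 15.5 to 35.7 M counts in the age experiment, 39.5 to 90.0 M in the day course and 53.1 to 170 M in the transgenic experiment. A floor of 3 counts corresponds to 0.084 to 0.19 CPM, 0.033 to 0.076 CPM and 0.018 to 0.056 CPM, which covers counting error only. No fold is given against a group at or under that floor. The 10 most abundant genes took 5.33 to 8.99%, 6.77 to 9.14% and 4.84 to 5.69% of counts. Replicate libraries differed far beyond sampling noise, with chi-square values per degree of freedom of 12.1 to 181 over 67 pairs, so no library was counted as a duplicate.

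The tests were checked on counts simulated from the real means, library sizes and dispersions with 67, 67 and 66 genes changed by 1.5, 2 and 4 times. At a 2-fold change, edgeR recovered 86.6% of changed genes for the age effect in O1 (12308 genes run, 5.36% of calls false), 91.0% for time of day in B3 (11759 genes, 1.21% false) and 100% for mhc>timeless against mhc (12501 genes, 6.16% false). At a 1.5-fold change it recovered 59.7%, 53.7% and 98.5% for these comparisons. Alternatives were RLE factors, no filter, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, a cosine curve for time of day, and a preset correlation for the lists. Chosen after the data were seen were thinning of libraries to equal totals, ZT18 alone, subsets of time points, and leaving out libraries rich in testis or photoreceptor RNA. Other splits of the same libraries were drawn up to 100 per comparison.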

Results

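Gene expression was measured in skeletal muscle of the parental fly strain B3 and of the delayed-aging strains O1 and O3, at 1 and 6 weeks of age and, in separate libraries, at 4 times of the day. A further day course compared flies that overexpress timeless (tim) in muscle with their driver-only control. The 18 libraries of the age experiment held 15.5 to 35.7 M counts, with 15.5 to 31.6 M at 1 week and 25.6 to 35.7 M at 6 weeks. The 31 libraries of the strain day course held 39.5 to 90.0 M and the 23 transgenic libraries 53.1 to 170 M. In the transgenic experiment depth differed with genotype: mhc libraries at ZT0, ZT6 and ZT12 held 53.1 to 71.9 M counts, mhc libraries at ZT18 148 to 168 M, and mhc>timeless libraries 124 to 170 M. The series asks how muscle expression of the strains diverges with age and what part the muscle clock has in it.

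In the parental strain B3, genes of energy metabolism were lower at 6 weeks than at 1 week and proteasome genes were higher. Aconitase (Acon), an enzyme of the citrate cycle, went from 4548 ± 90.7 to 1028 ± 29.7 CPM (SD, n = 3 each), a log2 change of -2.15. All 39 measured nuclear genes of the respiratory chain fell, with a median log2 change of -1.34 (39 adjusted over the list alone), among them cytochrome c (Cyt-c-p, -1.99) and the succinate dehydrogenase subunit SdhA (-1.81). Of the citrate cycle genes 9 of 10 fell, with a median of -1.33 (10 adjusted over the list alone), and of the glycolysis and glycogen genes 16 of 18, with a median of -1.04 (16 adjusted over the list alone), including aldolase (Ald, -1.84) and glycogen phosphorylase (GlyP, -1.81). All 31 proteasome genes rose, with a median of 1.08 (31 adjusted over the list alone). The core subunit gene Prosbeta3 went from 64.9 ± 4.38 to 188 ± 12.4 CPM (log2 change 1.54 ± 0.0802) and the regulatory subunit gene Rpn2 changed by 1.30. With an estimated correlation the lists had adjusted p = 0.00188 for the respiratory chain, 0.00172 for the citrate cycle, 0.00172 for glycolysis and glycogen, and 0.0422 for the proteasome (camera). The proteasome was not called without the filter (0.0783) or without library 1, 2 or 3 of B3 at 1 week (0.0621, 0.0536 and 0.0543), over a range of 6.17e-41 to 0.0783 across alternatives.

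Immune genes were among the largest rises in B3. Drosomycin (Drs), an antifungal peptide gene, went from 71.7 ± 15.9 to 1127 ± 188 CPM (log2 change 3.98 ± 0.256, adjusted p = 2.33e-08), Defensin (Def) changed by 3.50 ± 0.245 and Attacin-B (AttB) by 3.38 ± 0.70. Of 31 antimicrobial and humoral immune genes 24 rose and PGRP-SC1a fell (26 called when adjusted over the list alone), but the list as a whole was not called, with adjusted p = 0.107 with an estimated correlation. Among 26 chaperone genes 11 rose and 3 fell (15 adjusted over the list alone), with Hsp23 at 2.52 ± 0.348, the mitochondrial chaperone gene Hsc70-5 at 1.32 ± 0.0936 and CG7409 at -2.45 ± 0.128 (adjusted p of the list 0.697 with an estimated correlation). Of 28 sarcomere genes 20 fell and 2 rose (23 adjusted over the list alone), with flightin (fln) at -2.73 ± 0.144, the actin gene Act57B at 1.58 ± 0.107 and adjusted p = 0.0643 with an estimated correlation. Of 92 cytosolic ribosomal protein genes 81 rose and 1 fell (84 adjusted over the list alone, adjusted p = 0.281 with an estimated correlation), and of 71 mitochondrial ones 9 rose and 34 fell (45 adjusted over the list alone, adjusted p = 0.713). The largest falls were in digestive protease genes such as Jon99Fii, at 110 ± 15.4 CPM at 1 week and 0.733 CPM at 6 weeks (-7.21 ± 1.25), and in CG13026 (-6.5 ± 0.406). Over all 12445 genes tested, edgeR called 5196, 2710 higher and 2486 lower at 6 weeks, of which 1202 changed at least 2-fold.

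The other lists showed few or mixed changes with age in B3, and none was called with an estimated correlation. Among the core clock genes 4 of 8 were called (4 adjusted over the list alone): period (per) rose by 0.54 and clockwork orange (cwo) by 0.28, while cryptochrome (cry) went from 186 ± 15.9 to 122 ± 12.0 CPM (-0.61, adjusted p = 5.16e-05) and Pdp1 changed by -0.21. These genes change over the day, and the labels give no hour of harvest for the age libraries. A different hour at the 2 ages can therefore not be told apart from an age effect on them. Of 13 clock regulators 6 rose and 1 fell (7 adjusted over the list alone, adjusted p = 0.546), and of 12 clock output genes 2 rose and 3 fell (5 adjusted over the list alone, adjusted p = 0.993). Of 17 autophagy genes 1 rose and 2 fell (2 adjusted over the list alone, adjusted p = 0.993). Of 16 genes of insulin, FOXO and TOR signalling 7 rose and 1 fell (9 adjusted over the list alone, adjusted p = 0.480), with the kinase gene Akt1 at 1.14 ± 0.0648. Of 27 detoxification genes 9 rose and 5 fell (15 adjusted over the list alone, adjusted p = 0.697), of 9 secreted muscle factors 3 rose (3 adjusted over the list alone, adjusted p = 0.588), and of 12 lipid genes 2 fell (1 adjusted over the list alone, adjusted p = 0.993).

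Markers of other tissues also moved with age and strain. The summed level of 26 gut genes was 10700 ± 2020 CPM in B3 at 1 week and 3800 ± 564 CPM at 6 weeks, 22 of them called lower (24 adjusted over the list alone), against 16100 ± 2620 and 12200 ± 1200 CPM in O1 and 10600 ± 2760 and 9860 ± 3810 CPM in O3. Fat body genes summed to 12300 and 9840 CPM in B3, 8670 and 8420 CPM in O1 and 6760 and 9900 CPM in O3 at 1 and 6 weeks, and hemocyte genes to 3690 and 3280, 2570 and 2550, and 2440 and 3310 CPM. Testis genes summed to 33.1 ± 30.5 and 3.15 ± 2.59 CPM in B3, 166 ± 143 and 105 ± 80.9 CPM in O1, and 466 ± 517 and 7.18 ± 4.28 CPM in O3, and accessory gland genes to 42.7 and 20.4, 72.4 and 134, and 1210 ± 1120 and 207 CPM (at most 332 CPM in a library) in the 3 strains. Yolk protein genes rose from 11 ± 6.43 to 124 ± 50.2 CPM in O1, from 3.05 to 14.3 CPM in B3 and from 3.58 to 7.18 CPM in O3. Neuronal genes went from 1850 to 1230 CPM in B3 (11 of 13 lower), from 1690 to 1380 CPM in O1 and from 2120 to 1380 CPM in O3. Cuticle genes summed to 563 and 607 CPM in B3 at 1 and 6 weeks, with 3 genes called higher and 3 lower, but to 399 and 302 CPM in O1 (3 lower) and 433 and 316 CPM in O3 (2 higher, 5 lower). Glia genes summed to 2340 and 1990, 2370 and 1960, and 2420 and 2080 CPM in B3, O1 and O3, photoreceptor genes to 175 and 189, 193 and 218, and 264 and 333 CPM, and trachea genes to 189 and 216, 163 and 158, and 176 and 168 CPM. Ovary genes summed to 0.631 and 1.44, 0.548 and 1.2, and 0.608 and 1.05 CPM, and male dosage compensation RNAs to 695 and 593, 704 and 566, and 764 and 672 CPM. Reads in no annotated feature took 25.6 ± 2.15% at 1 week and 15.7 ± 1.27% at 6 weeks (SD, n = 9 each).

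In O1, muscle contraction and energy genes fell with age. The calcium pump gene Ca-P60A, which returns calcium to the sarcoplasmic reticulum, went from 10820 ± 633 to 1533 ± 108 CPM (-2.82), and the calcium-binding protein gene Scp1 from 3685 ± 731 to 331 ± 16.6 CPM (-3.48 ± 0.117). Of 28 sarcomere genes 25 fell and 1 rose (27 adjusted over the list alone), with myofilin (Mf) at -2.78 and the troponin C gene TpnC4 at -2.31. The respiratory chain had 35 of 39 genes lower (median -0.95, 35 adjusted over the list alone), the citrate cycle 8 of 10 (median -0.66, 8 adjusted over the list alone, citrate synthase kdn at -1.95) and glycolysis and glycogen 15 lower and 1 higher of 18 (median -1.05, 16 adjusted over the list alone, Gapdh1 at -2.32). These lists had adjusted p = 0.000869, 0.00217, 0.00217 and 0.000601 with an estimated correlation. Of the 31 proteasome genes 17 rose, with a median of 0.29 (18 adjusted over the list alone, adjusted p = 0.652 with an estimated correlation). Of the 31 immune genes Def rose by 0.68 and Drs went from 275 ± 57.3 to 120 ± 36.8 CPM (-1.20), and 29 were not called (1 adjusted over the list alone, adjusted p = 0.881). The yolk protein gene Yp1 had the largest rise, from 3.00 ± 1.67 to 68.9 ± 29.8 CPM (4.53 ± 0.443). In all, 2830 genes were called, 1291 higher and 1539 lower, of which 411 changed at least 2-fold. Without the testis-rich libraries 2 and 3 of O1 at 1 week part of these calls was lost, and a larger share of calls was lower. That fit left only library 1 of the group, which stood apart from libraries 2 and 3. Chi-square values per degree of freedom were 98.3 and 79.7 against them and 13.4 between them. The loss can therefore not be laid to testis RNA alone.

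In O3, 25 of 28 sarcomere genes fell with age, with a median of -1.25 (25 adjusted over the list alone). TpnC4 went from 1243 ± 107 to 160 ± 15.6 CPM (-2.96 ± 0.107) and the actin gene Act79B changed by -2.03. The respiratory chain had 32 genes lower and 2 higher (median -0.85, 35 adjusted over the list alone), the citrate cycle 8 lower and 2 higher (median -0.67, 10 adjusted over the list alone, kdn at -2.57), and glycolysis and glycogen 15 lower and 1 higher (median -1.16, 16 adjusted over the list alone, Gapdh1 at -2.76). Adjusted p was 0.000972 for the sarcomere, 0.0152 for the respiratory chain, 0.0113 for the citrate cycle and 0.000972 for glycolysis and glycogen with an estimated correlation. Without the filter the respiratory chain and the citrate cycle were not called (0.0623 each, the highest of ranges from 6.28e-49 and 2.37e-14). Of 31 proteasome genes 30 rose (30 adjusted over the list alone), with a median of 0.48 and adjusted p = 0.322 with an estimated correlation. The larval serum protein gene Lsp1alpha rose from 7.38 to 77.0 CPM (3.38), and tim rose from 479 ± 90.8 to 714 ± 52.7 CPM (0.58, adjusted p = 0.0187). For tim a different hour of harvest at the 2 ages cannot be told apart from an age effect. All 11 measured testis genes were lower at 6 weeks, with a median of -6.02, and 1826 of the 2182 genes that changed at least 2-fold were lower. Over all genes 6237 were called, 2832 higher and 3405 lower. The count was 4144 without library 2 of O3 at 1 week. Libraries 1 and 2 of that group held the most testis RNA (374 and 1023 CPM, against 1.75 CPM in library 3). Without both, part of the calls was lost, but that fit left only library 3 of the group. Chi-square values per degree of freedom were 53.7 and 107 for library 3 against libraries 1 and 2, and 41.2 between those. Testis RNA alone can therefore not be named as the cause of the loss.

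**Figure D1:**
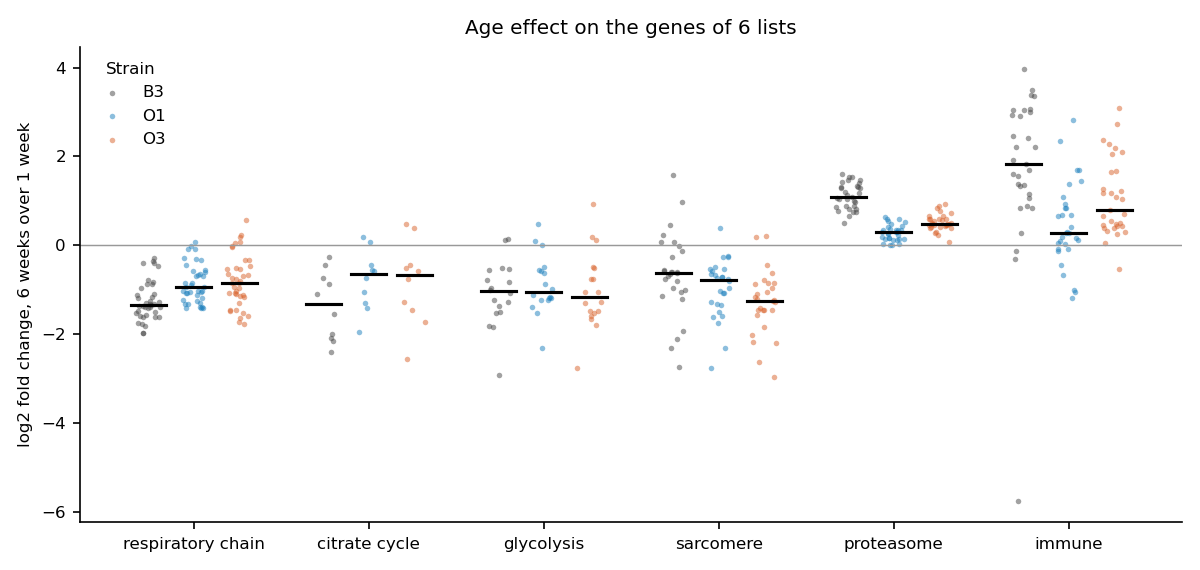
Log2 fold change from 1 to 6 weeks (y axis) of each gene (points) of 6 lists in B3, O1 and O3, with horizontal bars at the list medians. Respiratory chain medians lay at -1.34, -0.95 and -0.85, and proteasome medians at 1.08, 0.29 and 0.48 in B3, O1 and O3.

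Many age changes recurred across strains whose age effects share no libraries. In B3 and O1, 2089 genes were called in the same direction, where independent lists would share 589, and 92 in opposite directions (Pearson r = 0.475 across genes, which are not independent replicates). B3 and O3 shared 2888 genes (1297 for independent lists, 249 opposite, r = 0.615), and O1 and O3 shared 2304 (715 for independent lists, 8 opposite, r = 0.530). Without the testis-rich libraries of O3 at 1 week B3 and O3 shared 1747, and without those of O1 (libraries 2 and 3) O1 shared 1273 with B3 and 1311 with O3. In every strain the age groups also differed in reads outside features (20.8 to 27.9% at 1 week, 13.0 to 17.6% at 6 weeks) and in the share of the 10 most abundant genes (7.51 to 8.99% and 5.33 to 5.87%). In all 3 strains 865 genes rose and 950 fell, where independent lists would give 64 and 84.

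At 1 week, O1 and O3 differed from B3 in clock genes. In O1, tim stood at 696 ± 82.4 CPM against 234 ± 57.1 CPM in B3 (log2 difference 1.57 ± 0.186, adjusted p = 3.93e-05), per was higher by 1.04 ± 0.133, and Clk, whose product activates both, lower at -0.92 ± 0.207. In O3 the differences were 1.03 for tim (adjusted p = 0.000808), 0.62 for per and -0.55 for Clk (adjusted p = 0.0488). The labels give no hour of harvest for these libraries, and unequal hours between strains could also give such differences. Of 39 respiratory chain genes 38 were higher in each strain (39 in O1 and 38 in O3 adjusted over the list alone, medians 0.43 and 0.57), with adjusted p = 0.170 in O1 and 0.109 in O3 with an estimated correlation. Immune genes were lower, 14 of 31 in O1 and 21 in O3 (19 and 27 called when adjusted over the list alone, adjusted p = 0.471 and 0.122), with Diptericin (Dpt) at -3.76 in O1, while Drs was higher by 1.94 ± 0.236 in O1. The noncoding RNA gene CR43459 was at 1470 ± 115 CPM in B3, 25 CPM in O1 and 21.6 CPM in O3. The cell cycle gene CycB (3.50) and the small heat shock gene Hsp26 (2.92) were among the largest rises in O1, and lectin-24A and the glutathione transferase gene GstD3 (-3.69) among the falls. The receptor gene mthl12 was at 23.1 and 38.1 CPM in O1 and O3 and below the floor of 3 counts in B3. In O3 the accessory gland gene Acp26Aa was at 82.7 ± 75.8 CPM, against 2.41 CPM in B3. There were 2956 calls in O1 (1276 higher, 1680 lower) and 4475 in O3 (2398 higher, 2077 lower). The count for O3 was 2706 without B3 library 3, 2937 without B3 library 2 and 2957 without O3 library 2. Part of the O3 calls was also lost without its 2 testis-rich libraries, in a fit that left only library 3 of the group. Without the testis-rich libraries 2 and 3 of O1 the balance of its higher and lower calls turned, and part of the calls was lost. That fit left only library 1 of O1, which stood apart from libraries 2 and 3. Chi-square values per degree of freedom were 98.3 and 79.7 against them and 13.4 between them. Testis RNA and the deviation of library 1 can therefore not be told apart there.

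At 6 weeks antimicrobial peptide genes were far lower in O1 and O3, with CecB at -6.14 and -5.75 and CecA1 at -4.49 and -5.03 (158 CPM in B3, 7.04 CPM in O1 and 4.88 CPM in O3). Of 31 immune genes 27 were lower in O1 and 28 in O3 (30 and 29 called when adjusted over the list alone), with adjusted p = 0.0505 and 0.0649 with an estimated correlation. All 39 respiratory chain genes were higher in both strains, by medians of 0.81 and 1.03 (39 each adjusted over the list alone), with the cytochrome oxidase gene cype at 1.21 in O1 and 1.59 in O3. Citrate cycle genes were higher, 10 of 10 in O1 and 9 of 10 in O3 (10 each adjusted over the list alone), with Acon at 1.47 and 1.64 and the oxoglutarate dehydrogenase gene Nc73EF at 1.85 and 1.86. Adjusted p with an estimated correlation was 0.0486 and 0.0189 for the respiratory chain and 0.0486 and 0.0341 for the citrate cycle in O1 and O3. Of these only the respiratory chain in O3 was called without the filter, and the citrate cycle was not called in O1 without library 1 of B3 (0.0502, range 1.51e-10 to 0.0599) or in O3 without library 3 of B3 or library 1 of O3 (0.0511 and 0.0543, range 1.28e-11 to 0.0598). All 31 proteasome genes were lower in both strains, by medians of -0.94 and -0.85 (31 each adjusted over the list alone, adjusted p = 0.0777 and 0.131). Among signalling genes the insulin-binding protein gene ImpL2 was at -1.09 ± 0.237 in O1 and -1.30 ± 0.238 in O3. tim was higher by 1.23 and 1.18 and cry by 0.55 and 0.86. Both genes change over the day, and the hour of harvest of these libraries is not known. Gut protease genes were also higher, with Jon25Biii at 6.19 in O1 and Jon99Ci at 5.78 in O3, and 24 and 22 of 26 gut genes called higher. In O1 5523 genes were called (2468 higher, 3055 lower) and in O3 5012 (2492 higher, 2520 lower). At this age B3 also differed from O1 and O3 in read quality, without overlap. Reads in no annotated feature took 16.4 to 17.6% in B3, 13 to 15.7% in O1 and 15.5 to 16.1% in O3. Ambiguous reads took 2.85 to 2.99%, 3.16 to 3.42% and 3.32 to 3.57%. Reads without a unique position came to 0.653 to 0.686%, 0.483 to 0.598% and 0.505 to 0.541% of the counted number. Whether this adds to the strain differences was not tested.

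**Figure D2:**
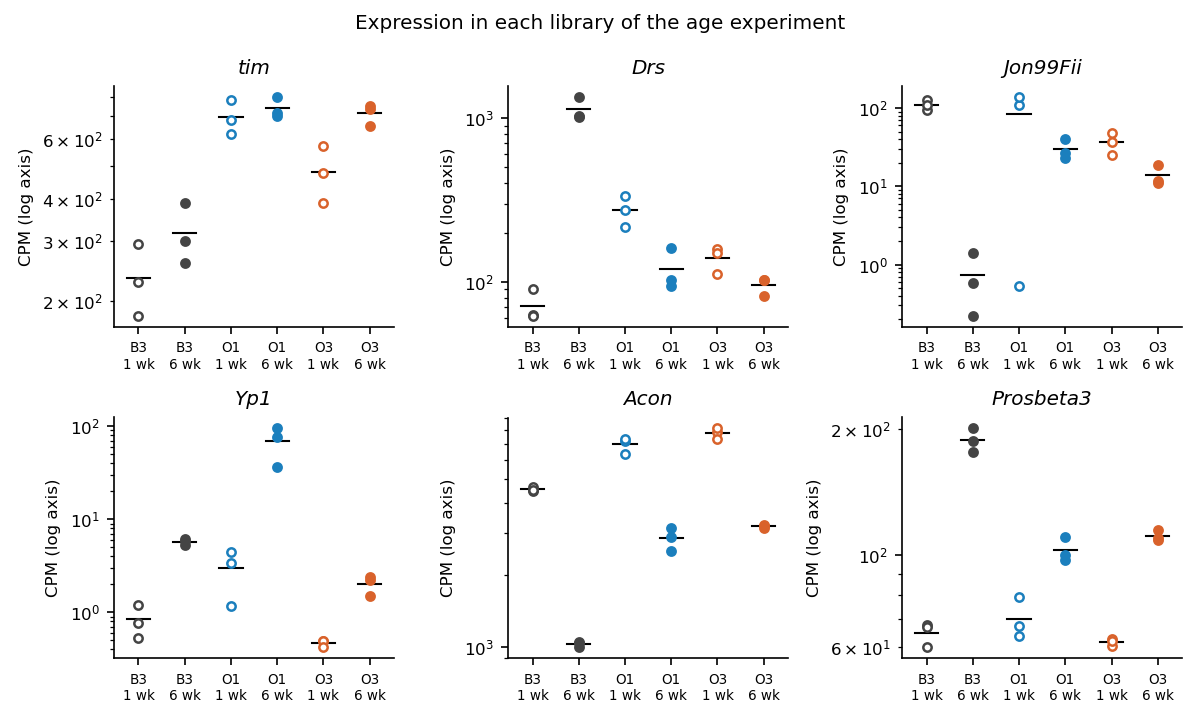
Expression (CPM, log axis) of 6 genes in each library of the age experiment, with horizontal bars at the group means (n = 3; open symbols 1 week, filled symbols 6 weeks). Drs reached a mean of 1127 CPM in B3 at 6 weeks, against 120 in O1 and 96.1 in O3, and Jon99Fii fell to 0.733 in the same B3 libraries.

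The age effect itself was tested against that of B3. Drs had an interaction of -5.17 ± 0.340 in O1 (adjusted p = 2.72e-06) and -4.52 ± 0.336 in O3. The light receptor gene cry, lower with age in B3, had interactions of 0.72 in O1 and 0.75 in O3, which unequal hours of harvest could also give. All 31 proteasome genes had a lower age change in O1 (31 adjusted over the list alone, median -0.79, adjusted p = 0.0682 with an estimated correlation) and 23 in O3 (27 adjusted over the list alone, median -0.61, adjusted p = 0.207). Among citrate cycle genes 7 of 10 had a higher age change in each strain (9 and 8 adjusted over the list alone, adjusted p = 0.0682 and 0.139), with Nc73EF at 1.44 ± 0.138 in O1. Of 28 sarcomere genes 22 had a lower age change in O3 than in B3 and 1 a higher one (25 called when adjusted over the list alone), but the list was not called (adjusted p = 0.0707). The flight muscle actin gene Act88F, with an interaction of -3.19 ± 0.219, changed in opposite directions and went from 596 ± 133 to 1178 ± 171 CPM in B3 and from 998 ± 73.1 to 217 ± 34.3 CPM in O3. In O1 1776 genes were called (745 higher, 1031 lower) and in O3 2196 (1252 higher, 944 lower). The balance in O3 was not stable, with 1199 higher and 1200 lower under RLE factors and 1446 and 1593 with DESeq2. Lower calls also outnumbered higher ones without the testis-rich libraries of O3 at 1 week, a fit that left a single library in that group.

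Over the day course, strain differences were measured in separate libraries. O1 and O3 carried far less RNA of the antifungal peptide gene Metchnikowin (Mtk), at 3.62 to 6.5 CPM and 2.47 to 5.45 CPM across the time points against 102 to 196 CPM in B3. The gene lectin-37Da (-6.10 in O1) and CR43459 (-5.54 in O1, -5.74 in O3) were also lower. The gut protease gene Jon99Fi stood at 30.8 to 70.3 CPM in B3 and at most 0.129 CPM in O1 and O3. In the age experiment, library 1 of O1 at 1 week lay at -9.49 relative to libraries 2 and 3 for this gene (log2 scale). O1 thus carried Jon99Fi RNA in some libraries, and a difference in dissected gut tissue was not told apart from a strain difference. The cytochrome P450 gene Cyp4d1 was higher by 3.50 in O1 and 3.69 in O3, CG9192 by 4.0 and 3.74, and CycB by 4.02 in O1. All 39 respiratory chain genes were higher in both strains, by medians of 0.72 and 0.53 (39 each adjusted over the list alone, adjusted p = 0.127 and 0.184 with an estimated correlation), and all 30 measured proteasome genes lower, by -0.35 and -0.31 (30 each adjusted over the list alone, adjusted p = 0.175 and 0.259). Immune genes were lower, 28 of 30 in O1 and 26 in O3 (28 and 26 adjusted over the list alone, adjusted p = 0.127 and 0.184). The translation repressor gene Thor was at -1.10 ± 0.0831 and -1.27 ± 0.0745 and the cytokine gene upd3 at -2.68 ± 0.276 and -3.37 ± 0.238. Mean tim differed little, by 0.08 in O1 (adjusted p = 0.103) and 0.10 in O3 (adjusted p = 0.0266), while cwo was lower at -0.40 and -0.47. Fat body genes summed to 9280 to 13800 CPM in B3, 6250 to 8060 CPM in O1 and 5980 to 7170 CPM in O3. Of 13 neuronal genes 8 were higher in O1 and 10 in O3 with 0 lower, of 22 gut genes 5 were higher and 8 lower in O1 and 6 and 10 in O3, of 8 hemocyte genes 4 were lower in O1 and 2 higher and 3 lower in O3, and of 12 testis genes 4 were higher in O3. There were 6903 calls in O1 (3514 higher, 3389 lower, 977 at least 2-fold) and 7466 in O3 (3847 higher, 3619 lower, 1347 at least 2-fold). The O3 libraries also differed from B3 in read quality, without overlap. Reads in no annotated feature took 12 to 16.5% in O3, 10.2 to 11.6% in B3 and 7.11 to 12.5% in O1. Reads without a unique position came to 30.8 to 45.4% of the counted number in O3, 24.4 to 29.4% in B3 and 19.8 to 33.8% in O1. Whether this adds to the strain differences was not tested.

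Strain differences at 1 week recurred in the day course. For O1, 2350 genes were called in the same direction in both experiments and 63 in opposite directions, where independent lists would share 845 (Pearson r = 0.411, Spearman rho = 0.536 across genes). For O3 the counts were 3267 and 82, against 1323 (r = 0.641, rho = 0.702), with 1589 in the same direction without the testis-rich libraries of O3. O1 and O3 also differed from B3 in the same direction in 2122 genes at 1 week, 4031 at 6 weeks and 5337 over the day, where independent lists would share 526, 1113 and 2097. The 1 week count was 1275 and 1231 without the testis-rich libraries of O3 or O1. These contrasts share the B3 libraries, and unchanged groups simulated against them gave correlations of 0.519, 0.511 and 0.488 against 0.849, 0.681 and 0.622 observed. The covariance of the fold changes exceeded the simulated one by 1.16, 0.866 and 0.558. For the age by strain contrasts 1225 genes were called in the same direction and 0 in opposite directions, where independent lists would share 153. Unchanged groups simulated against the B3 libraries shared 0, but groups without change yield hardly any calls, so this cannot decide on sharing. The age change of B3 enters both contrasts with the same sign, so a change in B3 alone would also be shared. The correlation of 0.225 lay below the 0.516 that shared B3 libraries gave with unchanged groups, and the covariance differed by 0.0328. With separate sets of B3 libraries for O1 and O3 over the day, 4365 and 4288 genes were shared (r = 0.571 and 0.584).

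Daily rhythms of the core clock were large in all 3 strains. In B3, tim ran from 115 ± 11.4 CPM at ZT6 (n = 2) to 955 ± 57.0 CPM at ZT18 (n = 2), an amplitude of 3.06 on the log2 scale (adjusted p = 4.95e-16), and it had 3.13 in O1 and 3.43 in O3. per peaked at ZT18 with amplitudes of 1.73, 1.77 and 1.66, Clk at ZT0 with 1.67, 1.47 and 1.71, and cry at ZT6 with 1.28, 1.98 and 1.70 in B3, O1 and O3. Of the 8 core clock genes 7 were called in each strain (7 adjusted over the list alone), and cyc was not (adjusted p = 0.503, 0.277 and 0.682). Juvenile hormone esterase (Jhe), which degrades juvenile hormone, peaked at ZT0 with amplitudes of 5.15, 5.46 and 5.93, from 33.7 CPM at ZT0 to 0.956 CPM at ZT18 in B3. The glucuronosyltransferase gene Ugt35b (2.24, 2.16 and 2.00) also peaked at ZT0 and CG14880 (1.28, 1.18 and 1.33) at ZT12. In total 1382 genes changed over the day in B3, 1341 in O1 and 2093 in O3, of which 250, 388 and 358 had at least a 2-fold amplitude. The count in O3 was 1372 without library 3 at ZT6 and 3463 without library 1 at ZT6, and a cosine curve called 572 in B3 and 1154 in O3.

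The daily profile differed between strains in few genes. At ZT12 tim was at 654 ± 19.7 CPM in B3, 897 CPM in O1 and 830 CPM in O3 (adjusted p of the interaction 6.16e-05 in O1 and 0.0293 in O3). The zinc finger gene cabut (cbt) was at 119 CPM in B3 at ZT12 against 238 CPM in O1 and 216 CPM in O3. The gene cln3 was highest at ZT18 in B3 (86.3 CPM) and at ZT12 in O1 (107 CPM) and O3 (93.6 CPM). CG12268 was lowest at ZT12 in B3 (9.79 CPM) and highest then in O1 (11.9 CPM) and O3 (11.4 CPM). In O1 172 genes were called and in O3 190, and 4 and 1 of the 8 core clock genes (6 and 4 adjusted over the list alone). The count in O1 was 76 without the lone ZT18 library, 110 without O1 library 2 at ZT0, 105 and 96 without B3 library 1 or 3 at ZT12, 88, 86 and 101 without O1 library 1, 2 or 3 at ZT12, 499 with DESeq2 and 26 with a cosine curve. The count in O3 was 1110 without O3 library 1 at ZT6, 100 without B3 library 1 at ZT12, 126 and 98 without O3 library 1 or 2 at ZT12, 122 without O3 library 3 at ZT18, 658 with DESeq2 and 23 with a cosine curve.

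**Figure D3:**
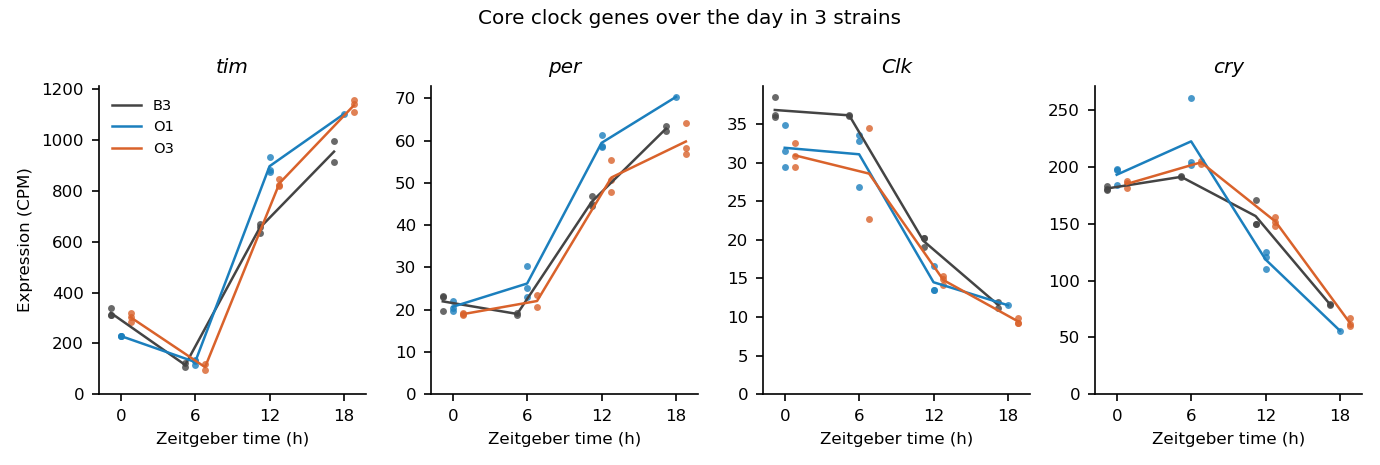
Expression (CPM) of tim, per, Clk and cry against zeitgeber time (hours) in B3, O1 and O3, with points for libraries and lines through the time-point means. At ZT12 the means of tim were 654 in B3, 897 in O1 and 830 in O3.

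In the transgenic experiment, tim was first read in every library. It stood at 284 ± 11.3 CPM at ZT0, 149 ± 6.06 CPM at ZT6, 273 ± 11.4 CPM at ZT12 and 778 ± 35.6 CPM at ZT18 in mhc, and at 1231 ± 25.6, 1018 ± 166, 1192 ± 192 and 1553 ± 82.9 CPM in mhc>timeless, where no library lay below 891 CPM, so each library followed its label. Over the day tim was higher in mhc>timeless by 2.00 ± 0.0529 (adjusted p = 2.32e-14). Clk was lower at -0.12 ± 0.0227 (adjusted p = 0.0013), and the other 6 core clock genes were not called (2 called when adjusted over the list alone), with per at 0.01 ± 0.0305. The gene white (w), whose mini form marks many fly transgenes, was at 9.22 to 12.5 CPM against 0.54 to 0.75 CPM in mhc (3.99 ± 0.221). Hsp70Bb was at 20.8 to 29.2 CPM against 4.30 to 6.91 CPM across libraries, the P450 gene Cyp6a2 higher by 1.42 and the maltase gene Mal-B2 by 1.17. CG42876 (-2.85), Lsp1alpha (-1.67) and CG9246 (-1.50) were lower.

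**Figure D4:**
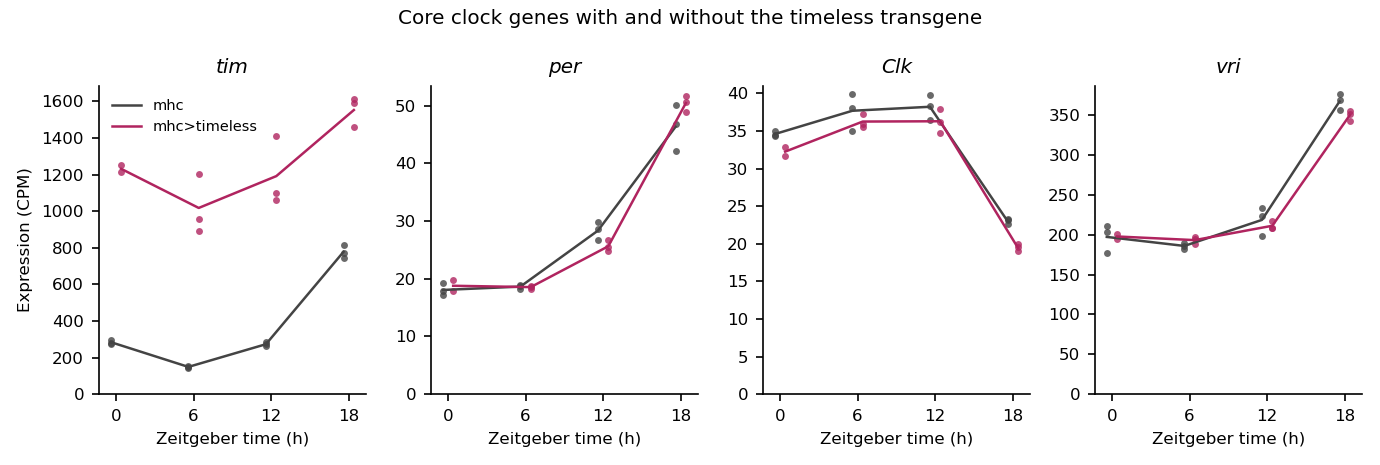
Expression (CPM) of tim, per, Clk and vri against zeitgeber time (hours) in mhc and mhc>timeless, with points for libraries and lines through the time-point means. Means of tim at ZT0 were 284 in mhc and 1231 in mhc>timeless, and the curves of per lay close together.

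Most other differences between the genotypes were small. Of 92 cytosolic ribosomal protein genes 61 were lower (70 adjusted over the list alone), by a median of -0.10, with adjusted p = 0.403 with an estimated correlation. Immune genes were lower in 7 and higher in 1 of 30 (15 adjusted over the list alone, adjusted p = 0.403), with Dpt at -1.95 ± 0.546, and among 26 chaperone genes 6 were higher and 2 lower (8 adjusted over the list alone, adjusted p = 0.403), with Hsp23 at 0.50 ± 0.0977. Of 14 accessory gland genes 5 were higher, with sums of 0.178 to 5.14 CPM in mhc groups and 0.599 to 34.7 CPM in mhc>timeless groups. Of 12727 genes tested 2346 were called, 1105 higher and 1241 lower, of which 120 changed at least 2-fold. At ZT18 alone, where both genotypes were sequenced deeply, 14 genes were called, among them tim (1.01 ± 0.0629, adjusted p = 0.00582), w, Hsp70Bb, CG42876 and CG9246. That fit had only 3 libraries per genotype and so less power, and 1341 genes had an unadjusted p under 0.05 in its F-tests.

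Daily rhythms were present in both transgenic lines. The amplitude of tim was 2.39 in mhc and 0.62 in mhc>timeless (adjusted p of the interaction 7.11e-05). The counts do not separate transgene reads from those of the fly's own tim. A steady transgene level would by itself lower the log2 amplitude, so a change in the rhythm of the fly's own tim was not shown. per peaked at ZT18 with amplitudes of 1.36 and 1.44 and Clk at ZT12 with 0.73 and 0.90. The chaperone gene Hsp83 was lowest at ZT12, at 641 ± 29.3 CPM in mhc and 629 ± 1.08 CPM in mhc>timeless, against 1084 to 1392 CPM at the other times. Jhe had amplitudes of 2.92 and 3.40 and Ugt35b of 1.84 and 2.05. Of the 8 core clock genes 7 were called in each line (7 adjusted over the list alone). In mhc 2871 genes were called, 241 with at least a 2-fold amplitude, and in mhc>timeless 2425, of which 331. A cosine curve called 1070 and 1041, and ZT0, ZT6 and ZT18 alone 1220 and 734. In mhc the calls peaked most often at ZT18 (1113 genes, against 596 in mhc>timeless), the time at which mhc was sequenced more deeply, and ZT0, ZT6 and ZT12 alone called 1688. Of 14 photoreceptor genes 13 were called in mhc and 12 in mhc>timeless, with sums of 1650 ± 2720 CPM in mhc at ZT12 and 2100 ± 3510 CPM in mhc>timeless at ZT18, each raised by 1 library.

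The interaction of time and genotype called 16 genes, 2410 at an unadjusted p under 0.05, with tim first. For tim, added transgene reads alone could give this interaction. The ubiquitin hydrolase gene Uch (adjusted p = 0.0134) was at 59.2, 64.8, 58.1 and 72.6 CPM at ZT0, ZT6, ZT12 and ZT18 in mhc and at 72.7 to 75.4 CPM in mhc>timeless. Prosbeta5 was at 260 to 281 CPM in mhc at ZT0, ZT6 and ZT12 and 356 CPM at ZT18, and at 334 to 369 CPM in mhc>timeless. In both cases the deeply sequenced mhc libraries of ZT18 lay near mhc>timeless. DESeq2 called 597 genes, a cosine curve 2, and 16 of the 23 single libraries moved the count by more than 1.5 times when left out, to between 2 and 49, with the lowest count without library 1 of mhc at ZT12 or library 1 or 3 of mhc at ZT18 and the highest without library 2 of mhc>timeless at ZT18.

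The genes called between the transgenic lines were compared with those called between strains over the day. With O1, 623 genes were called in the same direction and 930 in opposite directions, where independent lists would share 658 and 659 of 12061 genes (Pearson r = 0.0672, Spearman rho = -0.0464 across genes, 47.2% of genes with the same sign). With O3, 709 were in the same direction and 883 opposite, against 709 and 711 (r = 0.251, rho = 0.0578, 50.1% with the same sign).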

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

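The evenness of the splits was examined, and the tests of a strain-wide tim difference, of the gut share and of a gut segment were chosen only after the results were seen, as were thinning, ZT18 alone and leaving out libraries rich in testis or photoreceptor RNA.

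The age effect differed between strains by a test of the difference itself. Against B3, 1776 genes had another age effect in O1 and 2196 in O3. In O1 the largest positive differences on the log2 scale were CG9463 (6.33), CG17475 (6.06), CG31266 (6.05), CG31267 (6.01) and CG9466 (5.76), and the largest negative ones Drs (-5.17), CG7567 (-3.05), Cyp6g2 (-2.89), Def (-2.83) and CG13422 (-2.60). In O3 they were CG9463 (6.91), Jon99Ci (5.82), Jon99Fii (5.81), PGRP-SC1a (5.81) and CG31267 (5.73), and CG12506 (-6.94), scpr-A (-5.78), scpr-B (-5.38), scpr-C (-5.35) and CG3964 (-4.74). These differences were not separated from shares of other tissues. Gut genes summed to 10700 CPM in B3 at 1 week and 3800 CPM at 6 weeks. In O3 testis genes went from 466 to 7.18 CPM and accessory gland genes from 1210 to 207 CPM. Of the core clock, cry differed by 0.72 in O1 and 0.75 in O3 and Pdp1 by 0.36 in O3, with no hour of harvest in the labels. Among 100 splits of the libraries into strains, 8 called as many genes as the labels for O1, the highest other split 5397 against 1776, and 7 for O3, the highest other 3707 against 2196, so chance was not excluded for either count. The split with 5397 points to a structure of the samples. Among the 41 splits that spread the strains evenly over the ages, the highest count was 0 for O1 and O3. Among 89 that were even or uneven by 0.667, where 2 is the highest value possible, it was 1852 for O1 and 2064 for O3. Evenness is the change between ages in the excess of true O1 or O3 libraries in the group named after that strain.

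The daily profile also differed by a direct test, in 172 genes for O1 and 190 for O3 against B3. Adjusted p in O1 was 6.16e-05 for tim, 0.0456 for per, 0.00416 for cry, 0.0263 for cwo, 4.58e-06 for l(1)G0148, 3.23e-05 for CG12268, 4.17e-05 for cln3, 6.02e-05 for CG14186 and 6.16e-05 for cbt. In O3 it was 0.0293 for tim, 9.81e-06 for CG12268, 3.54e-05 for cln3, 7.85e-05 for l(1)G0148, 0.000259 for CG15199 and 0.000259 for CG8112. Among 40 splits, 4 called as many genes as the labels for O1 (highest other 2632 against 172) and 6 for O3 (highest other 5811 against 190), so chance was not excluded. Here too the splits with more genes point to a structure of the samples, as each other split with as many genes spread the strains unevenly over the times, by at least 1.67 for O1 and 1.33 for O3 on the same scale. Among the 2 and 17 splits nearest to even the highest counts were 1 and 0.

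Between genotypes, 16 genes had another daily profile on the log2 scale. Adjusted p was 7.11e-05 for tim, 0.00322 for CG1598, 0.0134 for Uch, 0.0262 for CG9676 and 0.0262 for CG8343. For tim a steady level of transgene reads could give this by itself. CG9676 stood at 79.9 ± 17.4 CPM in mhc at ZT12 (n = 3) and at 60.4 CPM in library 3 of mhc>timeless at ZT18, against at most 0.779 CPM in the other libraries (SD). CG8343 had 179 ± 40.1 CPM and 88.3 CPM there, against at most 1.17 CPM. Of 100 splits 5 called as many genes, the highest other 222 against 16, so chance was not excluded. The other splits with as many genes again spread the genotypes unevenly over the times, by at least 2 on that scale, and the 50 splits nearest to even called at most 1 gene.

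In data outside the main measurement, the share of reads in no annotated feature was 9.84 percentage points higher at 1 week than at 6 weeks in the age experiment.

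The first pattern weighed is the set of 2346 genes called between mhc>timeless and mhc, whose libraries also differ in depth. Eye tissue in single libraries was argued against, since 84.4% of the calls were kept without library 3 of mhc at ZT12 and library 3 of mhc>timeless at ZT18, which held 4800 and 6159 CPM of photoreceptor RNA. Read number alone was argued against as the whole cause, since thinning to equal totals kept 1938 of the calls. Genes called at ZT0, ZT6 and ZT12 were read again at ZT18, where depths were similar. Their median change in the same direction was 0.377 of that at the other times, and 69.9% kept their direction. The ratio lay between the bounds set for and against an effect of depth. The genes were picked by the tests at the other times, so their sizes there are inflated by selection. A smaller change at ZT18 would thus follow from a constant genotype effect too, and the ratio cannot decide on an effect of depth. A difference in library preparation that went with depth could therefore not be told apart from an effect of timeless for most small changes, while tim, w, Hsp70Bb, CG42876 and CG9246 were also called at ZT18 alone and the genotype stays an open explanation.

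The second pattern is the higher tim and per and lower Clk in O1 and O3 in the age libraries, for which the labels give no hour of harvest. A tim level set higher at all times was argued against, since tim in O1 exceeded B3 in the day course by at most 0.456 on the log2 scale, at ZT12, and lay below it at ZT0, against 1.57 ± 0.186 at 1 week. Clk lay below B3 at each time of the day course, by -0.007 to -0.459 in O1 and -0.251 to -0.425 in O3. A lasting strain difference in Clk was therefore not argued against. Harvest at another hour met its preset bound in the pooled groups. There, 495 other daily genes were displaced along the interval from ZT6 to ZT12. Their displacement was 0.687 of that of the core clock genes (bootstrap 95% interval 0.381 to 1.01). The bootstrap drew only from the 495 genes and held the core clock displacement fixed. It thus leaves out the spread between libraries and between core genes. The span from ZT6 to ZT12 was chosen as the best fit to those core genes. At 6 weeks the displacements also hold any age effect that differs between strains. Single genes followed the interval loosely, with correlations across the other daily genes of 0.402 in O1 and 0.2 in O3 at 1 week and 0.222 in both at 6 weeks. In every group tim, per and vri went along the interval. At 6 weeks cry went against it, at 0.708 in O1 and 0.928 in O3 where B3 changed by -0.29. So did Clk in O3 at 6 weeks, at 0.057 against -0.866 in B3. In O3 at 1 week Pdp1 went against the interval, at -0.138 where B3 changed by 0.87, as did cry at 0.174. The gene cwo was displaced by 0.467 to 0.813 across the groups, beyond its change of 0.156 in B3. The groups were uneven, with displacements of other and core genes of 0.409 and 0.609 in O1 and 0.161 and 0.348 in O3 at 1 week, and 0.322 and 0.44 in O1 and 0.314 and 0.359 in O3 at 6 weeks, so O3 at 1 week alone fell short of that bound. O1 and O3 libraries may thus have been taken later in the clock's day than B3 libraries, and an earlier clock stays open only as a part of the difference unless flies of the age experiment, whose phase was not measured, were further ahead than those of the day course, where tim peaked at 16 ± 0.1 h in O1 and 16.4 ± 0.3 h in O3 against 16.8 ± 0.3 h in B3.

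The third pattern is the fall of gut enzyme genes in B3 between 1 and 6 weeks. For a smaller share of gut tissue as a whole, 14 Jon protease genes were set against Amy-p, Amy-d and Mal-A1. The median change of the former lay at -4.64 relative to that of the latter on the log2 scale. Amy-p, Amy-d and Mal-A1 had the smallest falls of the 26 gut genes, and the contrast was chosen after the results were seen. It therefore cannot decide on a smaller share of gut tissue. The falls of the 26 genes ran from -0.603 to -6.27, so they were not by a common factor. Loss of a gut segment from the dissected tissue was left open by a Spearman correlation of 0.355 across gut genes between the B3 age change and the deviation of library 1 of O1 at 1 week, in which part of these genes lie near 0. The 10 genes near 0 in that library had a median change of -4.62 in B3, against -1.98 for the others. An age change of gut expression in B3 and a difference in dissection both stay possible and cannot be told apart here.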

How the results depend on the processing

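The ZT18, time-subset, testis, photoreceptor and thinning alternatives were chosen after the data were seen. Of 9169 values of named genes over all alternatives 8623 kept direction and side of the threshold, 530 no longer passed, 16 newly passed and 0 reversed, and of 3332 list tests 3195 kept both, 16 no longer passed, 121 newly passed and 0 reversed. No scaling moved the share of higher calls by over 10 percentage points. The list calls went from 16 to 118 with a preset correlation and to 10 without a filter, where the proteasome in B3, the respiratory chain and citrate cycle in O3, both in O1 against B3 at 6 weeks and the citrate cycle in O3 against B3 at 6 weeks were lost. DESeq2 called 499 genes (172 with edgeR) and 658 (190) for time by strain in O1 and O3 and 597 (16) for time by genotype. On simulated data 19.1 and 19.4% of DESeq2 calls for time of day in B3 and mhc were false, against 1.21 and 2.62% with edgeR. A cosine curve called 572 (1382 without it) in B3, 1154 (2093) in O3, 1070 (2871) in mhc and 1041 (2425) in mhc>timeless for time of day, 26 and 23 for time by strain and 2 for time by genotype. The 2-parameter curve leaves less room for other shapes, and otherwise the cause was not tested. Replicate numbers did not pair the samples: mean correlations of same-numbered samples were 0.060, 0.014 and -0.039 in the 3 experiments, and 46.7, 28.7 and 44.2% of pairs were over 0.1. The replicate block gave 105 for time by strain in O1 and moved no other count of calls by over 1.5 times. It left 12 of the 16 list calls, without the proteasome in B3, the respiratory chain and citrate cycle in O1 and the citrate cycle in O3 against B3 at 6 weeks. ZT18 alone called 14 genes between genotypes, against 2346, from 3 libraries per genotype and so with less power. With ZT0, ZT6 and ZT12 time of day called 1688 in mhc, and with ZT0, ZT6 and ZT18 1220 in mhc and 734 in mhc>timeless, from fewer libraries. Leaving out libraries 1 and 2 of O3 at 1 week gave 2333 (6237 with them) for age in O3, 1806 (4475) for O3 against B3 at 1 week, 1049 (2196) for age by strain, 1589 (3267) genes called alike for O3 in both experiments, 1275 (2122) shared by O1 and O3 at 1 week and 1747 (2888) age calls shared by B3 and O3. Leaving out libraries 2 and 3 of O1 at 1 week gave 1231 shared at 1 week and 1273 (2089) and 1311 (2304) age calls shared with B3 and O3. Single libraries left out moved O3 against B3 at 1 week to 2706 to 5725 (lowest without B3 library 3, with 2937 and 2957 without B3 or O3 library 2), age in O3 to 4144 to 6556 (lowest without O3 1 week library 2), time of day in O3 to 1372 to 3463 (without ZT6 library 3 or 1), time by strain in O1 to 76 to 210 (76 without the 1 O1 library at ZT18 and so without that time, 86, 88 and 101 without O1 ZT12 libraries 2, 1 and 3, 96 and 105 without B3 ZT12 libraries 3 and 1, 110 without O1 ZT0 library 2) and in O3 to 98 to 1110 (98 and 126 without O3 ZT12 libraries 2 and 1, 100 without B3 ZT12 library 1, 122 without O3 ZT18 library 3, 1110 without O3 ZT6 library 1). Time by genotype moved to 2 to 49: in mhc 10 and 3 without ZT0 libraries 1 and 3, 10 without ZT6 library 2, 2 and 3 without ZT12 libraries 1 and 2, and 2, 5 and 2 without ZT18 libraries 1, 2 and 3, and in mhc>timeless 3 without ZT0 library 3, 7, 27 and 6 without ZT6 libraries 1, 2 and 3, 7, 3 and 3 without ZT12 libraries 1, 2 and 3, and 49 without ZT18 library 2. Where a group was left with 1 library, it was assumed to vary like the other groups. Leaving out libraries 2 and 3 of O1 at 1 week left library 1, which stood apart from both (chi-square per degree of freedom 98.3 and 79.7, against 13.4 between them). The fits without libraries 1 and 2 of O3 at 1 week likewise left only library 3 (53.7 and 107 against them, 41.2 between them). Changes in all these fits thus cannot be laid to testis RNA alone. Thinning to equal totals, run in the age and transgenic experiments only, and leaving out the photoreceptor-rich transgenic libraries moved no count there by over 1.5 times. Depth limits the age experiment most, where 3 counts correspond to up to 0.19 CPM.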

Other observations

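The phases here were read from a cosine curve after the daily calls were seen.

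Lipid genes changed over the day in each line, in 8 of 12 genes in B3 and O1, 9 in O3 and 10 in mhc and mhc>timeless (11, 8, 11, 11 and 10 adjusted over the list alone). The diacylglycerol acyltransferase gene mdy peaked at ZT0 in all 5 lines, with amplitudes of 1.09, 0.79, 0.74, 0.74 and 0.78 on the log2 scale. The fatty acid synthase gene CG3523 peaked at ZT0 in B3 (0.94) and at ZT12 in O1 (1.22), O3 (1.18), mhc (0.99) and mhc>timeless (1.00). The acetyl-CoA carboxylase gene ACC peaked at ZT0 in the strains (0.45, 0.62 and 0.52) and at ZT12 in the transgenic lines (1.04 and 0.99), and ATPCL, which makes cytosolic acetyl-CoA, at ZT12 with 1.09 and 1.05 in the latter. The storage droplet protein gene Lsd-1 had 1.12 in O1. The daily profile of CG3523 differed from that of B3 in O1 (adjusted p = 0.026) and O3 (0.0106) by the direct test, that of ACC was not called (0.161 and 0.137), and profiles were not tested between experiments.

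Proteasome genes changed over the day in 14 of 30 genes in B3 and 15 in O3 (27 and 26 adjusted over the list alone), against 1 in O1, 6 in mhc and 0 in mhc>timeless (0, 4 and 0 adjusted over the list alone). Glycolysis and glycogen genes were called in 15 of 18 in O3 and 7 and 3 in B3 and O1 (18, 11 and 6 adjusted over the list alone). Heat shock and chaperone genes were called in 8, 7 and 11 of 25 in B3, O1 and O3 and in 13 and 12 of 26 in mhc and mhc>timeless (13, 9, 13, 16 and 13 adjusted over the list alone). In the transgenic lines DnaJ-1, a partner of Hsp70, was also lowest at ZT12, at 126 and 132 CPM. Cytosolic ribosomal protein genes were called in 25 of 92 in mhc>timeless and 5 in mhc (50 and 0 adjusted over the list alone). By the direct test of the daily profile with edgeR, 0 of 30 proteasome genes differed from B3 in O1 or O3 (0 adjusted over the list alone), so a different proteasome rhythm between strains was not shown. Between genotypes 0 of 92 cytosolic ribosomal protein genes were called over all genes and 22 adjusted over the list alone. Of 18 glycolysis and glycogen genes 1 differed in each of O1 and O3 (2 and 4 adjusted over the list alone). Heat shock and chaperone genes differed in 3 of 25 in O1 and 4 in O3 (6 each adjusted over the list alone).

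Daily genes recurred across lines. B3 and O1 shared 594 called genes, where independent lists would share 151, B3 and O3 796 (235), O1 and O3 831 (228), and mhc and mhc>timeless 1482 (547). All 3 strains shared 503 (25.7) and all 5 lines 304 (1.2).

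The cosine peak of tim lay at 16.8 ± 0.3 h in B3, 16 ± 0.1 h in O1, 16.4 ± 0.3 h in O3, 18.1 ± 0.2 h in mhc and 18.4 ± 0.9 h in mhc>timeless (SE, n = 10, 10, 11, 12 and 11 libraries). For per it lay at 15.9 ± 0.2, 14.6 ± 0.4, 15.1 ± 0.2, 16.2 ± 0.5 and 17.1 ± 0.7 h.

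Splits of the libraries other than the labelled one were counted for each comparison. For the 7 contrasts of age and of strain at one age, 10 splits exist, too few for a share under 0.05. The labels and the highest other split called 5196 and 0 for age in B3, 2830 and 2 in O1, 6237 and 944 in O3, 2956 and 0 for O1 and 4475 and 842 for O3 against B3 at 1 week, and 5523 and 0 and 5012 and 0 at 6 weeks. The labelled split alone was as high, a share under 0.05, for O1 over the day (6903 against 3847, 40 splits) and O3 over the day (7466 against 3732). The same held for time of day in B3 (1382 against 448, 30 splits) and O3 (2093 against 413), and for mhc>timeless against mhc (2346 against 1164, 100 splits). It also held for time of day in mhc (2871 against 714, 60 splits) and mhc>timeless (2425 against 1388). No share below 1 of the splits drawn could be reached, and shares were not adjusted over comparisons, so chance was not excluded. For time of day in O1 the labelled split was also the only 1 of 30 as high. The margin was narrow there (1341 against 1322) and lay within the 942 to 1398 of single libraries left out, so that count was not set apart from chance.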
